A study of Caenorhabditis elegans with 10 samples.

How the data were processed

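RNA from whole wdr-23 mutant and N2 animals, 200 to 500 worms per sample and mostly L4 larvae, was hybridised to Affymetrix C. elegans arrays from 250 ng of total RNA. Animals had fed on bacteria carrying a control or a skn-1 RNAi plasmid, induced with 0.2% lactose under 50 ug/ml carbenicillin. The 10 arrays were biological replicates of 3 groups: N2 with control RNAi (n = 3), wdr-23 with control RNAi (n = 4) and wdr-23 with skn-1 RNAi (n = 3). No scan dates or batches are given, and detection calls were not used here.

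The deposited intensity values are linear MAS5 signals, per the authors' processing notes, which give no version. In the values, each array's mean after trimming 2% of probe sets at each end was 500.11 to 500.14, so each array had been scaled to one level. Of 22625 probe sets, 77 control probe sets were left out of the comparisons. A single gene was named for 20766 probe sets (17118 genes), several genes for 887 and none for 895. Gene symbols were compared with reference tables by gene number for 20701 probe sets, and 0 symbols changed. No pair of arrays was identical, and the number of arrays limits the precision.

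Signals were taken to log2 after adding a pseudocount of 19, the 20th percentile of all signals rounded. The lowest 30% of probe sets by mean log2 value (5.71 or less, 6765 probe sets) were left out, and 15783 were tested. Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, 16.4 total degrees of freedom), with the 3 groups in one fit and no replicate block. The replicate numbers did not pair the arrays throughout: correlations of residuals between arrays of the same number ran from -0.16 to 0.18 and those of other pairs from -0.17 to 0.17. Between N2 and wdr-23 skn-1 RNAi the same-number pairs were at 0.11, -0.03 and 0.15 for replicates 1, 2 and 3. A replicate effect shared by those groups is therefore not excluded, and a replicate block was run as an alternative. The p values were adjusted by Benjamini and Hochberg over all tested probe sets in each comparison, and a probe set was called at an adjusted p under 0.05. Folds are powers of 2 of the fitted log2 change and so are smaller than the ratio of signals in dim groups. Means and SDs are of the signals. Other computations used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

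Of the 12061 genes tested, each was represented by its probe set with the highest mean log2 value. The 34 gene lists, written from memory before the data were examined, as were the comparisons, the naming rule and the alternatives, covered SKN-1 readouts and regulators, detoxification and redox families, stress and immune responses, lipid metabolism, cuticle and moulting, germ line and growth, and tissues. They were tested with camera (limma) at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. Lists needed at least 5 tested members. With the preset correlation 16, 17 and 20 lists were called in the comparisons of mutant with N2, skn-1 RNAi with control RNAi, and mutant with skn-1 RNAi with N2. With the estimated correlation 2, 5 and 7 were. The limma test fry, which asks whether a list's genes move on balance one way (directional) or in either direction (mixed) and does not compare them with other genes, was run as an alternative. The signs of median, mean and test differed in 7, 5 and 5 lists, 0 of them called. The readout gene aip-1 was not found on the array by name. Of the 14 SKN-1 readout genes on the array, 13 were bright enough to test, and 9 of the 14 are also in another list.

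Genes were named by a rule. For each comparison these were the 10 largest rises and 10 largest falls among called, representative probe sets of 1 gene whose groups did not overlap (5 and 5 for the mutant with skn-1 RNAi against N2), wdr-23, skn-1, all SKN-1 readout genes, and up to 2 called members with the largest rise and 2 with the largest fall in each list. For genes that rose in the mutant and fell with skn-1 RNAi, the 10 with the largest of the smaller change were taken. Genes named outside this rule, because 5 or fewer members of a list were called, were chosen after their values were seen.

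The overlap of both comparisons with the mutant control arrays was set against independent lists and all splits of those arrays into separate pairs. The correlation and covariance of the changes were also set against 100 simulations of unchanged groups sharing those arrays. The fit was tested on 5 simulated data sets with the group sizes of the data, 200 of 15783 probe sets changed and independent normal noise. For mutant against N2 it recovered 28% of changes of 0.5 (log2), 83.2% of changes of 1 and 98.8% of changes of 2, and false calls were 3.93% of calls. The real comparison called 4344 probe sets, and genes that vary together were not simulated, so these rates need not hold in it. In 20 simulated data sets with 1 list raised by 0.5, camera with the preset correlation called that list 20 times and called 63 of 660 other lists. False list calls thus outnumbered true ones in this test, so a list called with the preset correlation alone may well be a false call. Alternatives were other pseudocounts (4.75 and 76), quantile normalization, median centring, no filter or the lowest 50% left out, probe sets with a suffix in their identifier left out, 1 probe set per gene, no intensity trend, robust eBayes, array weights, only the groups compared, a replicate block, and each array left out in turn. For the overlap, stricter thresholds were also tried.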

Results

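Gene expression was measured in whole Caenorhabditis elegans, most of them L4 larvae, on 10 Affymetrix arrays in 3 groups. N2, the laboratory wild type, fed control RNAi bacteria gave 3 arrays. The wdr-23 mutants fed control RNAi bacteria gave 4, and wdr-23 mutants fed skn-1 RNAi bacteria gave 3. WDR-23 is a WD-repeat protein that marks SKN-1 for removal through a cullin ubiquitin ligase, and SKN-1 is the worm relative of the Nrf factors that switch on detoxification genes. Array signals ran from 0.0533 to 25046, with array medians from 113 to 139.7. The first principal component, 52.6% of the variance, separated the groups. Its scores were -37.4 to -30.1 in N2, -18.9 to -13.5 in the mutant with skn-1 RNAi and 34.7 to 40.04 in the mutant with control RNAi. No N2 animals with skn-1 RNAi were measured, so whether skn-1 RNAi acts differently in the 2 genotypes cannot be tested. The number of arrays limits the precision, and the median standard error of a log2 change was 0.152 for both comparisons with the 4-array group and 0.163 for the other.

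The wdr-23 transcript, on its 1 probe set, was 3.72-fold higher in the mutant than in N2, with signals of 3259 ± 453 (SD, n = 4) and 865 ± 152 (SD, n = 3), and fell to 902 ± 18.6 (SD, n = 3) with skn-1 RNAi. The log2 changes were 1.89 (SE 0.13, adjusted p = 1.14e-08) and -1.82 (SE 0.13, adjusted p = 2.9e-08), and the 4 mutant control arrays lay above the other 6. Where the probes lie relative to the deleted part of the gene is not given, so this signal says nothing about the genotype labels. The skn-1 transcript, on the brightest of its 3 probe sets, fell 1.78-fold with skn-1 RNAi, from 474 ± 70.1 (SD, n = 4) to 257 ± 28 (SD, n = 3), a log2 change of -0.83 (SE 0.14, adjusted p = 0.000708). The other skn-1 probe sets fell as well, with log2 changes of -0.96 (adjusted p = 0.000123) and -0.72 (adjusted p = 0.00522). Between mutant and N2 on control RNAi, skn-1 itself did not pass the test on any probe set, with log2 changes of 0.06, 0.31 and 0.30.

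**Figure D1:**
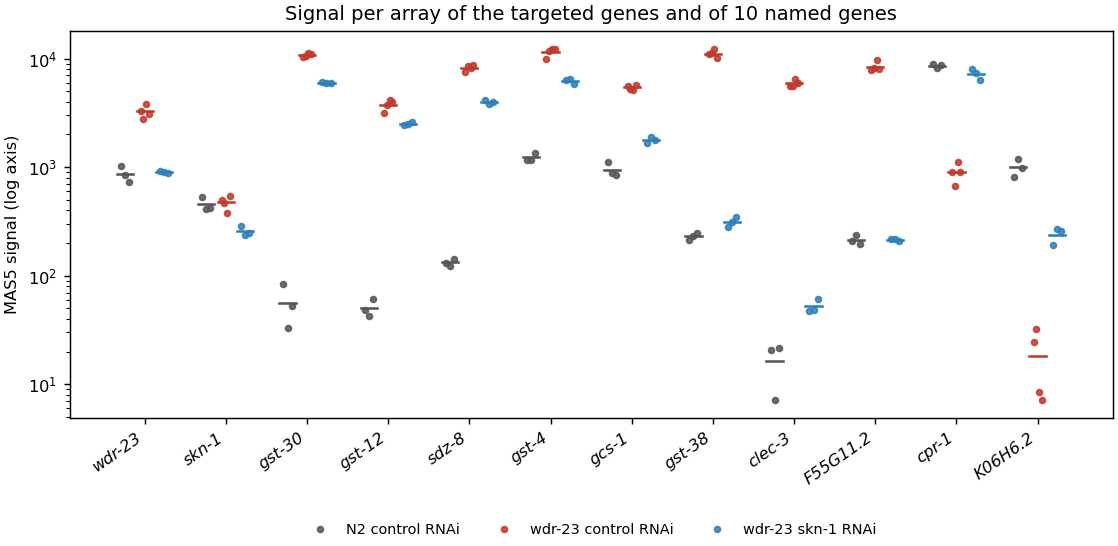
MAS5 signal on a log axis for wdr-23, skn-1 and 10 named genes, with 1 point per array and a bar at the mean of each group (n = 3, 4 and 3). The wdr-23 signals of the mutant on control RNAi, 2784 to 3858, lie above all other arrays, while gst-30 stays near 6019 and F55G11.2 returns to 214 with skn-1 RNAi.

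Loss of wdr-23, compared on control RNAi in both genotypes, asks what changes when skn-1 is left in place. Of the 10 largest rises, 5 were in genes named as glutathione S-transferases and 1 in a lectin gene. The glutathione S-transferase gst-30 rose from a signal of 56.4 ± 25.8 (SD, n = 3) to 10810 ± 467 (SD, n = 4), 149-fold with the pseudocount of 19 added, with a log2 change of 7.22 (SE 0.16, adjusted p = 2.23e-15). The lectin gene clec-3 rose 171-fold, from 16.44 ± 8.01 to 5929 ± 455, and W06H8.2 rose 170-fold, from 18.6 ± 8.41 to 6297 ± 696. The other large rises were T19D12.3 (108-fold), gst-40 (107-fold), gsto-2 (64.2-fold), nxnr-1 (63.5-fold), sdz-8 (54.4-fold), gst-12 (54.2-fold) and gst-38 (44.7-fold). In each of these 10 genes every mutant array lay above every N2 array, and the largest of their adjusted p values was 5.06e-15. Where the lower signal is near the pseudocount, the fold understates the ratio of the signals.

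Among the falls, K06H6.2 dropped most, from 993 ± 188 (SD, n = 3) in N2 to 18.15 ± 12.32 (SD, n = 4) in the mutant, a log2 change of -4.81 (SE 0.22, adjusted p = 4.7e-11). Y41C4A.32 was 22.7-fold lower, cTel55X.1 16.03-fold, warf-1 13.4-fold and rips-1 10.7-fold. The lysozyme gene lys-6 was 10.2-fold lower, and cpr-1, a cathepsin B-like protease, went from 8601 ± 417 to 893 ± 179, 9.58-fold lower. C30G12.2 (6.38-fold), the heat shock gene hsp-70 (5.72-fold) and K06H6.1 (5.64-fold) completed the 10 largest falls, each with every mutant array under every N2 array and an adjusted p of at most 1.59e-07.

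The lists of SKN-1 readouts and glutathione S-transferases were called higher. All 13 tested genes of the list of SKN-1 readouts, written from memory of earlier worm work, rose (13 adjusted over the list alone), with a median log2 change of 3.21 (camera adjusted p = 2.54e-27, 0.00255 with an estimated correlation). Among them gst-4, a common reporter of SKN-1 activity, went from 1232 ± 103 (SD, n = 3) to 11560 ± 1099 (SD, n = 4), and gcs-1, which makes the rate-limiting enzyme of glutathione synthesis, from 944 ± 140 to 5445 ± 288. The rest of that list ran from ptps-1 (3.48-fold), gst-7 (3.92-fold), nit-1 (5.62-fold), gst-13 (6.26-fold) and gst-10 (7.97-fold) to dhs-8 (17.9-fold), F56D5.3 (24.3-fold), gst-38, gst-12, sdz-8 and gst-30. Of 42 glutathione S-transferases, 28 rose and 2 fell (29 and 2 adjusted over the list alone), with a median log2 change of 1.24 (adjusted p = 1.77e-21, 0.01 with an estimated correlation). The exceptions were gst-19 (-1.69) and gst-9 (-0.83). In the list of glutathione, thioredoxin and NADPH supply, 9 of 21 rose and 1 fell (9 and 3 adjusted over the list alone), led by gcs-1 and by gss-1, glutathione synthetase (log2 change 1.38). That list was called at adjusted p = 0.023, with an adjusted p = 0.131 with an estimated correlation. Its median of 0.06 turned to -0.14 with median centring, where 7 rose and 6 fell, and it was not called without suffixed probe sets or without the intensity trend.

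Other detoxification families moved both ways. Of 53 UDP-glucuronosyltransferases, 17 rose and 14 fell (18 and 16 adjusted over the list alone, list adjusted p = 0.297), from ugt-38 (log2 change 4.90) and ugt-10 (3.14) to ugt-62 (-1.25) and ugt-29 (-1.05). Their median of 0.15 turned to -0.01 after quantile normalization and -0.05 after median centring. Of 42 cytochrome P450s, 7 rose and 8 fell (7 and 8 adjusted over the list alone, list adjusted p = 0.463), with cyp-23A1 (1.14) and cyp-34A8 (-1.12) at the ends. Of 28 short-chain dehydrogenases, 8 rose and 4 fell (8 and 5 adjusted over the list alone, list adjusted p = 0.451), from dhs-8 (4.16) to dhs-25 (-1.25). Of 45 ABC transporters, 14 rose and 4 fell (15 and 4 adjusted over the list alone, list adjusted p = 0.0561), with mrp-1, a drug exporter, at 2.16 and pgp-4 at 1.64. After quantile normalization 9 of the transporters rose and 5 fell, and with median centring 6 rose and 8 fell. The same scalings gave 3 cytochrome P450s up with 11 and 13 down. In the list of superoxide dismutases, catalases and peroxidases, 6 of 20 rose and 2 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.594). Its glutathione peroxidases split, with gpx-2 (1.72) and gpx-1 (1.498) up and gpx-3 (-1.45) down, and the mitochondrial dismutase gene sod-3 was at -0.9998. Of 13 SKN-1 regulators, wdr-23 and mxl-3 (0.71) rose and mpk-1 (-0.49), brap-2 (-0.43) and ddb-1 fell (2 and 4 adjusted over the list alone, list adjusted p = 0.463). With median centring 2 rose and 5 fell. Neither mpk-1 nor brap-2 was called without N2 replicate 1 (-0.43 and -0.39) or wdr-23 control RNAi replicate 2 (-0.39 and -0.39), among other single arrays.

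Of 17 heat shock genes, 4 fell and 0 rose (4 adjusted over the list alone), with hsp-70 at -2.52 and the small heat shock genes hsp-16.41 at -2.14, hsp-16.2 at -2.003 and hsp-12.3 at -0.77 (list adjusted p = 0.000789, adjusted p = 0.123 with an estimated correlation). In the endoplasmic reticulum stress list 5 of 21 fell (5 adjusted over the list alone), among them the BiP genes hsp-4 (-1.07) and hsp-3 (-0.48), and the list was called at adjusted p = 0.00996 (adjusted p = 0.297 with an estimated correlation). Only pas-3 (-0.29) fell among 33 proteasome subunits (0 adjusted over the list alone), whose median was -0.14 (adjusted p = 0.00373, adjusted p = 0.297 with an estimated correlation). The pas-3 call ended without N2 replicate 2 or 3, wdr-23 control RNAi replicate 1 or 4, or any wdr-23 skn-1 RNAi array (-0.29 to -0.23), and after quantile normalization (-0.23). With median centring 25 proteasome subunits fell (median -0.34), as did 9 heat shock genes and 12 of the reticulum list. Neither the reticulum list nor the proteasome list was called after quantile normalization (medians -0.14 and -0.09) or without suffixed probe sets (-0.02 and -0.13). In the mitochondrial stress list, dve-1 (0.55) rose and spg-7 (-1.05) fell among 11 (1 and 1 adjusted over the list alone, list adjusted p = 0.146). The dve-1 call ended without N2 replicate 1 (0.51) or 3 (0.52) or wdr-23 control RNAi replicate 2 (0.41) or 4 (0.49). It also ended after quantile normalization (0.37) and with median centring (0.35), where 0 of the list rose and 6 fell.

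Of 30 intestinal immunity effectors, 9 rose and 10 fell (9 and 10 adjusted over the list alone, list adjusted p = 0.907), from dod-24 (log2 change 4.61) and the caenopore gene spp-12 (3.19) to lys-6 (-3.35) and fmo-2 (-1.86). Of 19 epidermal antimicrobial peptides, 5 rose and 2 fell (7 and 5 adjusted over the list alone, list adjusted p = 0.504), with fipr-26 at 1.37. Of 13 osmotic response genes, 6 rose (7 adjusted over the list alone, adjusted p = 0.000789, adjusted p = 0.115 with an estimated correlation), among them the inositol transporter gene hmit-1.1 (2.002) and the furrow collagen gene dpy-7 (1.70). In the metal list, cdr-1 (1.05), ttm-1 (0.62) and cdr-6 rose and cdr-4 (-1.09) fell among 13 (3 and 1 adjusted over the list alone, list adjusted p = 0.975). Of 15 genes of hypoxia and hydrogen sulfide, 3 rose and 5 fell (5 and 5 adjusted over the list alone, list adjusted p = 0.474), with cth-2 (0.9986) and cysl-2 (0.96) against sqrd-1 (-2.02), which encodes sulfide quinone oxidoreductase, and cysl-3 (-0.85). Of 17 DAF-16 targets, 5 rose and 4 fell (5 and 4 adjusted over the list alone, list adjusted p = 0.776), from asah-1 (2.74), an acid ceramidase gene, to the desaturase gene fat-5 (-1.38). With median centring 3 DAF-16 targets rose and 7 fell, and in the metal list 2 rose and 4 fell (median -0.07).

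Lipid genes and cuticle collagens went both ways as well. In fatty acid desaturation and synthesis 4 of 22 rose and 4 fell (4 and 6 adjusted over the list alone, list adjusted p = 0.0586). The desaturase genes fat-5, from 1582 ± 47.3 (SD, n = 3) to 597 ± 19.4 (SD, n = 4), and fat-6, from 7240 ± 699 to 3253 ± 169, fell, and elo-7 (0.74) rose. In fatty acid breakdown 6 of 44 rose and 12 fell (9 and 12 adjusted over the list alone, list adjusted p = 0.206), from acdh-4 (1.02) to acdh-2 (-1.25) and ech-9 (-1.90). Of 124 cuticle collagens, 25 rose and 15 fell (26 and 15 adjusted over the list alone, list adjusted p = 0.834), with col-76 (2.08) and dpy-7 against col-137 (-1.48) and col-156 (-1.37). With median centring the collagens turned to 18 up and 42 down (median -0.20). The same scaling gave 2 up and 12 down in fatty acid synthesis, and 3 and 16 in breakdown.

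Moulting genes rose, 33 of 64 against 3 that fell (35 and 3 adjusted over the list alone), with a median log2 change of 0.53 (adjusted p = 3.55e-07, adjusted p = 0.203 with an estimated correlation). The hedgehog-related genes wrt-2 (2.06) and wrt-10 (1.91) led. Spermatogenesis genes rose in 27 of 78 cases with 0 falls (29 and 0 adjusted over the list alone, adjusted p = 0.000398, adjusted p = 0.225 with an estimated correlation), led by nspd-9 (2.02). With median centring 16 rose and 4 fell (median 0.10). The next largest, spe-43 (0.9967), was not called without N2 replicate 1 (0.73) or 2 (0.81). Oocyte and eggshell genes fell in 16 of 25 cases with 0 rises (22 adjusted over the list alone), with a median of -0.35 (adjusted p = 1.96e-07, adjusted p = 0.203 with an estimated correlation), including the RNA-binding protein genes mex-1 (-0.65) and puf-5 (-0.57). Without N2 replicate 1 both were at smaller changes (-0.45 and -0.44) and not called, and mex-1 was not called without N2 replicate 2 (-0.66) or wdr-23 control RNAi replicate 2 (-0.54) or 3 (-0.60). DNA replication genes fell in 13 of 24 cases with 0 rises (18 adjusted over the list alone, adjusted p = 3.62e-07, adjusted p = 0.123 with an estimated correlation), including the origin recognition genes orc-1 (-0.77) and orc-2 (-0.72). Quantile normalization gave 8 falls and median centring 23. Of 30 germ line and meiosis genes, deps-1 (-0.82), cgh-1 (-0.57) and syp-3 fell (2 adjusted over the list alone, adjusted p = 0.000726, adjusted p = 0.19 with an estimated correlation). With median centring 20 of them fell. Of 7 yolk and adult markers, 4 fell, all of them vitellogenin genes (5 adjusted over the list alone, adjusted p = 0.00113, adjusted p = 0.297 with an estimated correlation). The strongest was vit-1, from 5473 ± 706 (SD, n = 3) to 1563 ± 349 (SD, n = 4). None of 61 ribosomal protein genes passed the test (0 adjusted over the list alone), but their list was called lower (median -0.14, adjusted p = 0.000161, adjusted p = 0.582 with an estimated correlation). After quantile normalization it was not (median -0.02), while with median centring 48 of the 61 genes fell (median -0.34).

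Of 45 neuropeptide genes, 27 rose and 0 fell (30 and 1 adjusted over the list alone), with a median log2 change of 0.55 (adjusted p = 5.04e-08, adjusted p = 0.131 with an estimated correlation), led by the insulin-like genes ins-35 (1.67) and ins-37 (1.17). Of 23 other neuron markers, 5 rose (5 adjusted over the list alone, list adjusted p = 0.0675), among them aex-3 (0.81) and the peptide-processing gene egl-21 (0.71). Pharynx markers rose in 10 of 27 cases against 1 fall (10 and 1 adjusted over the list alone, adjusted p = 0.0055, adjusted p = 0.297 with an estimated correlation), from phat-5 (1.90) to phat-3 (-1.27). Without suffixed probe sets the list was not called (median 0.20). Of 24 body-wall muscle genes, 3 rose (3 adjusted over the list alone, list adjusted p = 0.834), among them the twitchin gene unc-22 (0.88) and the MyoD relative hlh-1 (0.69), which was not called after quantile normalization (0.52) or without N2 replicate 2 (0.58). Of 23 intestine markers, 4 rose and 5 fell (4 and 5 adjusted over the list alone, list adjusted p = 0.154). The peptide transporter gene pept-1 (1.07) and the GATA factor gene elt-2 (0.76) rose there, and the cathepsin genes cpr-1 (-3.26) and cpr-4 (-1.49) fell. With median centring 2 rose and 10 fell in the intestine, and 2 and 5 in muscle.

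In all, 4344 of 15783 probe sets passed the test between mutant and N2, 2754 higher and 1590 lower, of which 583 and 131 changed at least 2-fold. Counted once per gene, 2273 genes were higher and 1229 lower among 12061. The groups did not overlap for 33.9% of probe sets, where chance gives 5.71%. Without N2 replicate 1 the total was 2848 and the lower count 890. Median centring of the arrays moved the log2 changes of the probe sets by a median of -0.20 and turned the split to 1671 higher and 4613 lower. Quantile normalization moved them by a median of -0.12 and gave 1944 and 1955. The direction of small changes therefore holds only relative to the deposited scaling.

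The second comparison asks which expression in the mutant depends on skn-1, by setting skn-1 RNAi against control RNAi in wdr-23 mutants. The ratio of 3' to 5' signal of the catalase control, a sign of RNA quality, differed without overlap (2.37 to 3.33 against 1.18 to 2.20), and those of the actin, Gapdh and ubiquitin controls overlapped. The lectin gene clec-3 fell most, from 5929 ± 455 (SD, n = 4) to 52.3 ± 7.80 (SD, n = 3), 83.6-fold, with a log2 change of -6.38 (SE 0.15, adjusted p = 2.25e-14). F55G11.2 went from 8447 ± 838 to 214 ± 5.11, gst-38 from 11140 ± 820 to 315 ± 31.1 and dod-17, a gene named for acting downstream of DAF-16, from 7544 ± 394 to 228 ± 7.60. Further falls were clec-2 (44.2-fold), F01D5.2 (35.9-fold), C32H11.3 (34.8-fold), the glucuronosyltransferase gene ugt-38 (32.9-fold), clec-163 (29.4-fold) and C32H11.4 (28.4-fold). Among the 10 largest rises, the cathepsin genes cpr-1 and cpr-4 rose 7.999-fold and 4.71-fold, the aspartyl protease gene asp-17 4.36-fold, the lysozyme genes lys-6 and ilys-5 6.92-fold and 4.41-fold, and vit-1 4.06-fold. K06H6.2 (7.16-fold), K09C6.9 (5.97-fold), F23F12.3 (4.30-fold) and C30G12.2 (4.25-fold) were the other large rises. In all 20 of these genes the arrays of the 2 groups did not overlap, and the largest adjusted p was 3.71e-05.

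The lists of SKN-1 readouts and glutathione S-transferases were called lower with skn-1 RNAi. All 13 SKN-1 readout genes fell (13 adjusted over the list alone), with a median log2 change of -1.41 (adjusted p = 2.84e-18, 0.00913 with an estimated correlation). Their falls ran from 1.45-fold in gst-7, 1.48-fold in gst-12, 1.79-fold in gst-30, 1.85-fold in gst-4 and 2.06-fold in sdz-8 to 9.16-fold in gst-13 and 33.5-fold in gst-38, with gcs-1 at 3.04-fold. The remaining members, F56D5.3, gst-10, ptps-1, nit-1 and dhs-8, had log2 changes of -1.27, -1.41, -1.82, -1.89 and -2.81. Of 42 glutathione S-transferases, 24 fell and 0 rose (27 and 1 adjusted over the list alone, adjusted p = 1.95e-11, 0.0442 with an estimated correlation). UDP-glucuronosyltransferases fell in 24 of 53 cases and rose in 7 (26 and 9 adjusted over the list alone, adjusted p = 4.42e-05, adjusted p = 0.0841 with an estimated correlation), from ugt-13 (-3.28) to ugt-53 (1.68). In the glutathione, thioredoxin and NADPH list 9 of 21 fell and 0 rose (9 and 2 adjusted over the list alone, adjusted p = 0.00791, adjusted p = 0.0759 with an estimated correlation), including gcs-1 (-1.60) and gss-1 (-1.08). The lists of cytochrome P450s (4 up and 9 down, 4 and 9 adjusted over the list alone), short-chain dehydrogenases (4 and 7, 4 and 7 adjusted over the list alone), ABC transporters (2 and 10, 2 and 11 adjusted over the list alone) and superoxide dismutases, catalases and peroxidases (1 and 4, 1 and 6 adjusted over the list alone) were not called, with adjusted p = 0.397, 0.168, 0.182 and 0.28. Median centring gave 6 transporters up and 8 down, and 8 and 5 of the P450s. Among the peroxidases and dismutases, the glutathione peroxidase genes gpx-1 (-1.60) and gpx-2 (-1.32) fell and sod-3 (0.66) rose. Of the SKN-1 regulators, wdr-23, skn-1 and mxl-3 (-1.37), a transcription factor gene, fell (1 and 3 adjusted over the list alone, list adjusted p = 0.889). With median centring 5 of that list rose and 3 fell. The same scaling gave 4 up and 7 down in the glutathione, thioredoxin and NADPH list.

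In the metal list 5 of 13 fell and 0 rose (8 adjusted over the list alone, adjusted p = 0.000644, 0.0442 with an estimated correlation), with the ferritin gene ftn-1 at -1.65 and the cadmium-response gene cdr-1 at -1.29. Without suffixed probe sets it was not called (median -0.33). Of 17 DAF-16 targets, 9 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 0.000587, 0.0442 with an estimated correlation), from asah-1 (-2.61) and ftn-1 to sod-3 and lys-7 (0.56). Osmotic response genes fell in 6 of 13 cases (6 adjusted over the list alone, adjusted p = 0.00412, adjusted p = 0.0759 with an estimated correlation), among them hmit-1.1 (-1.40) and dpy-7 (-1.08). That list too was not called without suffixed probe sets (median -0.43). Of 30 intestinal immunity effectors, 13 fell and 10 rose (14 and 10 adjusted over the list alone, list adjusted p = 0.121), with dod-24 (-3.72) and irg-3 (-3.56) against lys-6 (2.79) and lys-10 (1.91). Of 15 genes of hypoxia and hydrogen sulfide, 4 fell and 3 rose (4 and 3 adjusted over the list alone, list adjusted p = 0.513), with cysl-2 (-1.65) and rhy-1 (-1.21) against cth-1 (0.64) and sqrd-1 (0.55). The heat shock list was not called (3 up and 1 down, 3 and 1 adjusted over the list alone, adjusted p = 0.181), with hsp-16.41 at 0.75 and hsp-12.3 at 0.59. Neither was the mitochondrial stress list (4 up, 4 adjusted over the list alone, adjusted p = 0.0537), with hsp-6 at 0.61. The reticulum stress list (adjusted p = 0.957), the proteasome subunits (0.779) and the epidermal peptides (0.889) held 1, 2 and 3 called members (1, 1 and 2 adjusted over the list alone). With median centring 4 reticulum genes and 5 proteasome subunits rose.

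With skn-1 RNAi, moulting genes fell in 29 of 64 cases and rose in 1 (30 and 1 adjusted over the list alone, adjusted p = 2.25e-06, adjusted p = 0.196 with an estimated correlation), with ptr-22 at -1.65 and wrt-2 at -1.48. Germ line and meiosis genes rose in 13 of 30 cases with 0 falls (17 adjusted over the list alone, adjusted p = 5.95e-08, 0.0442 with an estimated correlation), including deps-1 (0.88) and the Argonaute gene csr-1 (0.58). With median centring 23 rose. DNA replication genes rose in 14 of 24 cases (16 adjusted over the list alone, adjusted p = 1.7e-06, adjusted p = 0.0759 with an estimated correlation), including orc-1 (0.73). Oocyte and eggshell genes rose in 9 of 25 (13 adjusted over the list alone, adjusted p = 4.87e-06, adjusted p = 0.208 with an estimated correlation), including cbd-1 (0.74), and in 21 with median centring. The same 4 vitellogenin genes that fell in the mutant rose (4 of 7 markers, 4 adjusted over the list alone, adjusted p = 0.00182, adjusted p = 0.279 with an estimated correlation). Sperm genes were not called (3 up and 2 down of 78, 1 and 1 adjusted over the list alone, adjusted p = 0.168), but with median centring 15 rose and 1 fell. Cuticle collagens were called lower, with 27 of 124 down and 5 up (30 and 5 adjusted over the list alone, adjusted p = 0.0415, adjusted p = 0.544 with an estimated correlation). Their median of -0.10 became 0.05 with median centring (13 up and 20 down), where the call ended. It also ended under 5 further settings and without N2 replicate 3 (-0.10), wdr-23 skn-1 RNAi replicate 3 (-0.10) or wdr-23 control RNAi replicate 4 (-0.07). Ribosomal protein genes were called higher as a list (median 0.10, 0 of 61 called singly and 0 adjusted over the list alone, adjusted p = 0.00182, adjusted p = 0.634 with an estimated correlation). That call ended after quantile normalization (0.02) and without wdr-23 skn-1 RNAi replicate 1 (0.04) or wdr-23 control RNAi replicate 1 (0.07). With median centring 15 of the 61 rose (0.24).

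Neuropeptide genes fell in 22 of 45 cases with 0 rises (25 and 1 adjusted over the list alone, adjusted p = 2.62e-06, adjusted p = 0.138 with an estimated correlation), with ins-35 at -2.07 and flp-1 at -0.74. Pharynx markers fell in 14 of 27 cases (16 adjusted over the list alone, adjusted p = 0.000185, adjusted p = 0.188 with an estimated correlation), with phat-5 at -1.11. With median centring 13 neuropeptide genes and 9 pharynx markers fell. Neuron markers fell in 5 of 23 cases (5 adjusted over the list alone, adjusted p = 0.0137, adjusted p = 0.0759 with an estimated correlation), with egl-21 at -0.81 and unc-13 at -0.72. They were not called as a list without suffixed probe sets (median -0.22). Body-wall muscle (2 of 24 down, 0 adjusted over the list alone, adjusted p = 0.0537), intestine (6 up and 6 down of 23, 6 and 6 adjusted over the list alone, adjusted p = 0.889), fatty acid synthesis (1 up and 3 down of 22, 1 and 3 adjusted over the list alone, adjusted p = 0.397) and fatty acid breakdown (8 up and 6 down of 44, 9 and 6 adjusted over the list alone, adjusted p = 0.592) were not called. Among their members cpr-1 rose, pept-1 (-1.11) and fat-5 (-0.62) fell, and ech-7 (1.12) rose.

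In all, 3558 probe sets passed the test between skn-1 RNAi and control RNAi in the mutant, 1577 higher and 1981 lower, with 80 and 404 changed at least 2-fold, or 1198 genes higher and 1578 lower. The groups did not overlap for 32.4% of probe sets, where chance gives 5.71%. The higher count was 884, 983 and 944 without wdr-23 skn-1 RNAi replicates 1, 2 and 3, and the total 2216 without replicate 1. Median centring moved the log2 changes by a median of 0.15 and gave 3463 higher and 1308 lower. Quantile normalization moved them by a median of 0.06 and gave 1712 and 1625.

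Of the 2754 probe sets that rose with loss of wdr-23, 1359 fell with skn-1 RNAi. Ranked by the smaller of both changes, the leading genes were clec-3, clec-2, F55G11.2, C32H11.3, gst-38, ugt-38, clec-163, C32H11.4, dod-17 and the mucin-like gene mul-1, whose signal was 16.7 ± 8.43 (SD, n = 3) in N2, 726 ± 62.1 (SD, n = 4) in the mutant and 18.3 ± 17.5 (SD, n = 3) with skn-1 RNAi. Of the 583 probe sets that rose at least 2-fold in the mutant, 499 (85.6%) fell with skn-1 RNAi. Of these 499, 315 were not called against N2, 159 were still called higher and 25 were called lower. Of the 131 that fell at least 2-fold, 87 (66.4%) rose with skn-1 RNAi. Of these, 54 were not called against N2, 31 were still called lower and 2 were called higher. A missing call does not show that a gene returned to its N2 level. The median share of the log2 change undone was 66.2% for the risen and 57.5% for the fallen. When the mutant control arrays were split so that neither comparison shared an array, it was 57.1% to 68.2% and 41.3% to 53.3%.

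**Figure D2:**
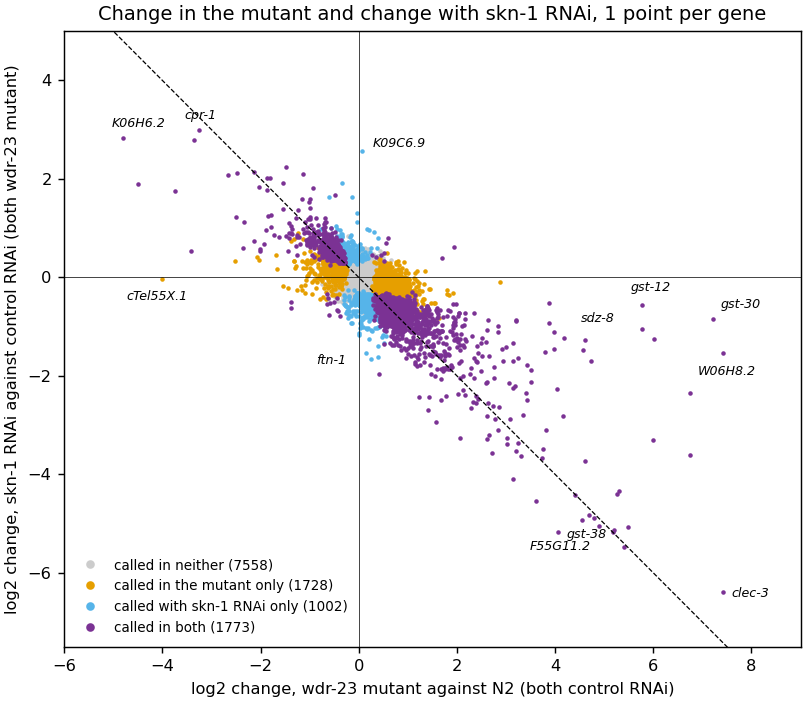
Log2 change between mutant and N2 on control RNAi (horizontal) against log2 change between skn-1 RNAi and control RNAi in the mutant (vertical), 1 point per gene, with calls at adjusted p under 0.05 in colour. Genes on the dashed line changed by equal and opposite amounts; F55G11.2 (5.18 and -5.18) lies on it, while gst-30 (7.22 and -0.84) and gst-12 (5.76 and -0.57) lie above it.

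Over all changes, 1359 probe sets rose in the mutant and fell with skn-1 RNAi, where independent lists would share 345.7, and 824 fell and then rose, where 158.9 would be shared. Only 10 rose in both and 19 fell in both, against 275.2 and 199.6. The mutant control arrays enter both comparisons with opposite signs, which by itself makes such an overlap larger. With those arrays split into separate pairs in all 6 ways, 834 to 955 probe sets rose and fell and 301 to 364 fell and rose, each above its independent overlap. The split does not remove a property common to all mutant control arrays. Their median signals, 134.8 to 139.7, lay above those of the other arrays, 113 to 125.3. The signal of the CreX spike-in control, 2318 to 3841 in them, lay below that of the N2 arrays (3911 to 5087). It overlapped that of the skn-1 RNAi arrays (3121 to 5218), and the BioB spike-in overlapped in all groups. An effect of these differences on the changes was not tested. Across probe sets, which are not independent replicates, the correlation of both log2 changes was -0.78 (simulated -0.43, split -0.70 to -0.66) and their covariance -0.202 (simulated -0.0134). The fell-then-rose overlap was 518 without N2 replicate 1 and 514 without wdr-23 skn-1 RNAi replicate 1. With median centring the overlaps were 876 and 2695.

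The third comparison, skn-1 RNAi in the mutant against N2 on control RNAi, shows what differed from wild type with skn-1 RNAi. Such differences were either left from the mutant or not called there, and the groups differ in both genotype and RNAi. The 3' to 5' ratios were also higher with skn-1 RNAi than in N2 without overlap for actin (1.29 to 1.57 against 1.12 to 1.21) and catalase (2.37 to 3.33 against 1.91 to 2.35). For the Gapdh and ubiquitin controls they overlapped. An effect of RNA quality on the changes was not tested. Among the 5 largest differences above N2, gst-30 remained 83.2-fold above N2, at 6019 ± 116 (SD, n = 3) against 56.4 ± 25.8 (SD, n = 3), a log2 change of 6.38 (SE 0.17, adjusted p = 1.08e-13). W06H8.2 was 58.8-fold higher, gst-12 36.6-fold, gsto-2 26.97-fold and sdz-8 26.4-fold. cTel55X.1 stayed low, at 23.4 ± 11.7 against 657 ± 24.4, and rips-1 (7.34-fold), Y41C4A.32 (6.10-fold), hsp-70 (4.53-fold) and fat-5 (3.997-fold) were the other largest differences below N2. In these 10 genes the arrays of the groups did not overlap, and the largest adjusted p was 7.68e-08. The skn-1 transcript was lower than in N2 on its brightest probe set (log2 change -0.77, adjusted p = 0.00577). Its other probe sets were at -0.65 (adjusted p = 0.0142) and -0.42 (adjusted p = 0.188, not called). The wdr-23 transcript was not called (0.07, adjusted p = 0.858).

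Of 13 SKN-1 readout genes, 11 were still higher than N2 and gst-13 was lower (11 and 1 adjusted over the list alone), with a median log2 change of 1.43 (adjusted p = 6.69e-24, 0.00403 with an estimated correlation). The weakest of the higher genes was gst-38 (0.42, adjusted p = 0.0482), whose call ended without any array but wdr-23 control RNAi replicate 4 (0.35 to 0.49), and ptps-1 was not called (-0.02, SE 0.15, adjusted p = 0.962). The gst-13 call ended without N2 replicate 3 (-0.47) or wdr-23 skn-1 RNAi replicate 3 (-0.53). The values between were 3.34 for F56D5.3, 2.32 for gst-4, 1.58 for gst-10, 1.43 for gst-7, 1.35 for dhs-8, 0.91 for gcs-1 and 0.60 for nit-1. Of 42 glutathione S-transferases, 21 were higher and 2 lower, gst-19 (-1.24) and gst-13 (23 and 4 adjusted over the list alone, adjusted p = 6.69e-24, 0.00498 with an estimated correlation). Heat shock genes stayed lower in 3 of 17 cases (3 adjusted over the list alone, adjusted p = 5.8e-05, 0.0403 with an estimated correlation), hsp-70 (-2.18), hsp-16.2 (-1.43) and hsp-16.41 (-1.39). The metal list was lower, 3 of 13 (5 adjusted over the list alone, adjusted p = 1.86e-06, 0.00818 with an estimated correlation), with ftn-1 at -1.41 and cdr-4 at -1.25. DAF-16 targets were lower in 6 of 17 cases (9 lower and 1 higher adjusted over the list alone, adjusted p = 6.95e-08, 0.00498 with an estimated correlation), with fat-5 at -1.999. Spermatogenesis genes were higher in 21 of 78 cases with 0 lower (30 adjusted over the list alone, adjusted p = 3.51e-12, 0.0403 with an estimated correlation), with nspd-9 at 1.23. Genes of hypoxia and hydrogen sulfide were lower in 5 of 15 cases and higher in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00189, 0.0403 with an estimated correlation), with sqrd-1 at -1.47 and cysl-3 at -0.95, but not without suffixed probe sets (median -0.18).

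Of the other called lists, UDP-glucuronosyltransferases were lower (6 down and 2 up of 53, 8 and 3 adjusted over the list alone, adjusted p = 4.48e-05, adjusted p = 0.0796 with an estimated correlation), with ugt-4 at -1.097 and ugt-53 at 1.19. Cytochrome P450s were lower (3 of 42, 3 adjusted over the list alone, adjusted p = 0.00497, adjusted p = 0.064 with an estimated correlation), with cyp-13B1 at -0.99. Intestinal immunity effectors were lower (7 down and 4 up of 30, 10 and 5 adjusted over the list alone, adjusted p = 0.00387, adjusted p = 0.064 with an estimated correlation), with clec-67 at -1.37 and clec-85 at -1.305 against lys-10 at 1.57. Fatty acid desaturation and synthesis was lower (3 of 22, 4 lower and 1 higher adjusted over the list alone, adjusted p = 0.000546, adjusted p = 0.0984 with an estimated correlation), the 3 being the desaturase genes fat-5, fat-6 (-1.40) and fat-7. The reticulum stress list (4 of 21 lower, 4 adjusted over the list alone, adjusted p = 7.66e-05, adjusted p = 0.138 with an estimated correlation), with hsp-4 at -0.88, and the proteasome list (1 of 33 lower, 0 adjusted over the list alone, adjusted p = 0.000256, adjusted p = 0.165 with an estimated correlation), with pbs-1 at -0.34, were called lower, but not without suffixed probe sets (medians -0.09 and -0.13). The pbs-1 call ended without any of the 6 arrays compared (-0.38 to -0.32) and after quantile normalization (-0.27), where 1 subunit was called higher and 0 lower.

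The remaining calls in this comparison were weak. Moulting genes (6 up and 1 down of 64, 7 and 2 adjusted over the list alone, adjusted p = 0.0492, adjusted p = 0.578 with an estimated correlation), with noah-1 at 1.001, lost their call under 6 settings and without N2 replicate 1 (median 0.05), wdr-23 skn-1 RNAi replicate 2 (0.11), wdr-23 skn-1 RNAi replicate 3 (0.14) or wdr-23 control RNAi replicate 1 (0.13). Neuropeptide genes (4 of 45 up, 5 adjusted over the list alone, adjusted p = 0.045, adjusted p = 0.479 with an estimated correlation), with ins-37 at 0.87, lost it without N2 replicate 1 (0.09), N2 replicate 2 (0.13) or wdr-23 skn-1 RNAi replicate 3 (0.08). Body-wall muscle (1 of 24 down, 1 adjusted over the list alone, adjusted p = 0.0391, adjusted p = 0.197 with an estimated correlation) and intestine (3 up and 3 down of 23, 3 and 3 adjusted over the list alone, adjusted p = 0.045, adjusted p = 0.305 with an estimated correlation) were called lower. Both lost it without N2 replicate 1 (-0.06 and -0.07), N2 replicate 2 (-0.07 and -0.15) or wdr-23 skn-1 RNAi replicate 3 (-0.07 and -0.09). Without suffixed probe sets both lost it too and turned direction, with the muscle median at 0.08 and the intestine list reversed in the mean (median -0.11). Germ line genes were called higher with 0 of 30 singly called (0 adjusted over the list alone, adjusted p = 0.0258, adjusted p = 0.267 with an estimated correlation), but not without N2 replicate 2 (0.15), N2 replicate 3 (0.13) or wdr-23 skn-1 RNAi replicate 1 (0.16). Osmotic response genes (2 of 13 up, 3 adjusted over the list alone, adjusted p = 0.0391, adjusted p = 0.158 with an estimated correlation), with dpy-9 at 0.68 (0.58 to 0.69 and not called without N2 replicate 2 or 3 or any wdr-23 skn-1 RNAi array), lost their call without N2 replicate 3 (0.30), wdr-23 skn-1 RNAi replicate 2 (0.28) or wdr-23 skn-1 RNAi replicate 3 (0.22). Cuticle collagens were called lower (7 down and 3 up of 124, 7 and 3 adjusted over the list alone, adjusted p = 0.00189, adjusted p = 0.339 with an estimated correlation), with col-36 at -0.86, but not without N2 replicate 2 (-0.03). The col-36 call ended without N2 replicate 1 (-0.81) or 2 (-0.75) or wdr-23 skn-1 RNAi replicate 2 (-0.73).

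The other 14 lists were not called in this comparison. For the oocyte and eggshell (25 tested), DNA replication (24), yolk and adult (7), neuron (23), mitochondrial stress (11), epidermal peptide (19) and ribosomal protein (61) lists, no member passed the test over all genes, and adjusted over the list alone 3 epidermal peptides rose. Among the others, acs-2 (-1.51), an acyl-CoA synthetase gene, and gpx-3 (-1.65) were lower, and mrp-1 (1.32) was higher.

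In all, 1001 probe sets differed between the mutant with skn-1 RNAi and N2, 613 higher and 388 lower, with 131 and 76 changed at least 2-fold, or 497 genes higher and 308 lower. The groups did not overlap for 26.2% of probe sets, where chance gives 10%. The total was 521 and the higher count 298 without wdr-23 skn-1 RNAi replicate 3, and the higher count was 346 without its replicate 2 and 334 without N2 replicate 1. The lower count was 223, 244 and 251 without wdr-23 skn-1 RNAi replicates 3, 2 and 1 and 257 and 244 without N2 replicates 1 and 2. Median centring gave 476 higher and 514 lower, and quantile normalization 457 and 415.

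**Figure D3:**
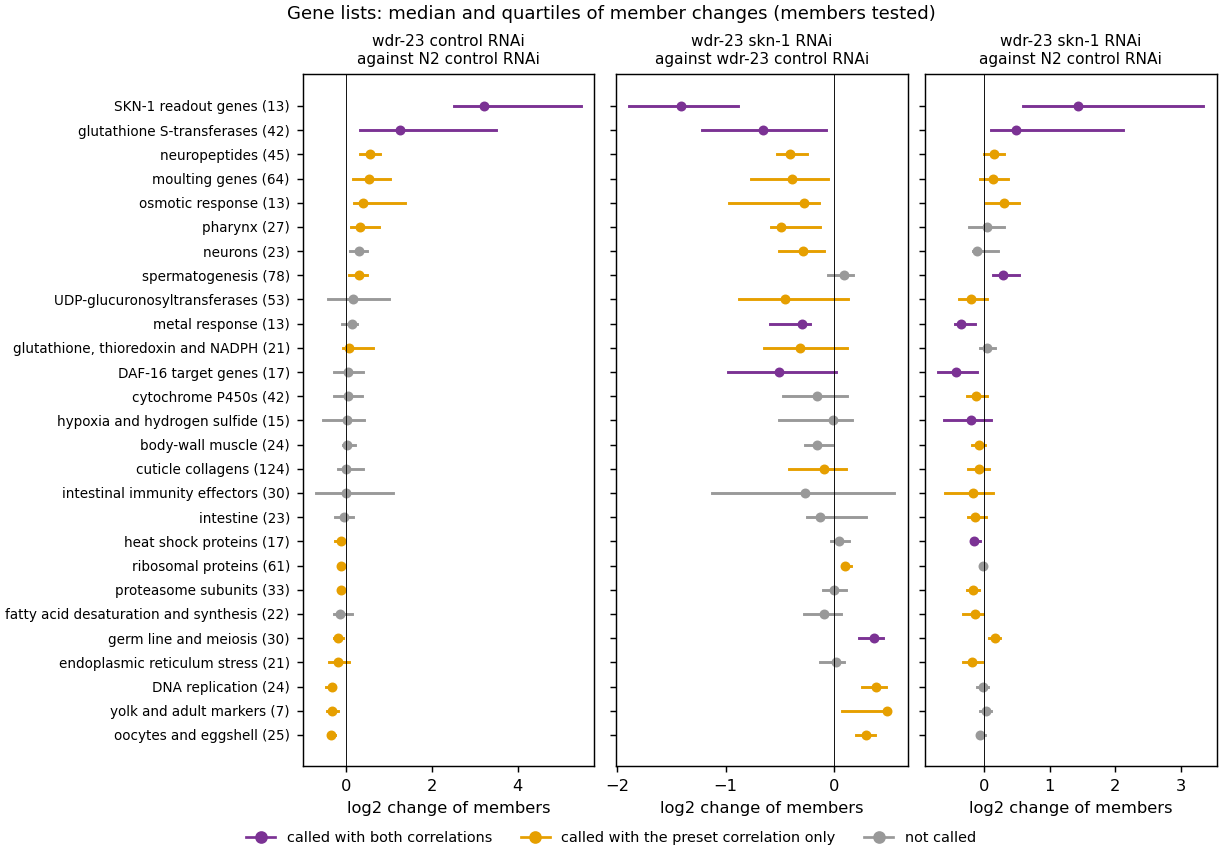
Median (point) and quartiles (bar) of the log2 changes of tested members of 27 gene lists in the 3 comparisons, with the number of members in brackets and colour for the set test. The SKN-1 readout median is 3.21 in the mutant, -1.41 with skn-1 RNAi and 1.43 against N2, and glutathione S-transferases follow at 1.24, -0.66 and 0.49.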

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

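All tests in this part were chosen only after the results were seen, except the within-group test of a younger stage and the test of variants near wdr-23.

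In the 4 arrays of the mutant on control RNAi, 7 named genes had 1 array far from the others, by the gap to its nearest neighbour as a share of the group's range. Chance gives about 10.4 among the 208 sets of values tested, which were the named genes and the quality measures of the arrays, so these do not mark an array. In replicate 3, gsto-2 was at 1245 against 1524 to 1536 (ratio 0.961), F55G11.2 at 9691 against 7867 to 8148 (0.832) and ftn-1 at 544 against 421.6 to 430.4 (0.92). In replicate 4, K06H6.1 was at 10.78 against 38.16 to 39.26 (0.972), fasn-1 at 3357 against 1859 to 2010 (0.869) and acdh-2 at 321 against 434.5 to 446.1 (0.919). In replicate 1, ins-35 was at 296.9 against 367.5 to 383.7 (0.83). Of these, the fasn-1 rise in the mutant was not called without replicate 4 (0.46), nor without N2 replicates 2 (0.45) or 3 (0.69).

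Control probe sets for C. elegans catalase, left out of the comparisons, were higher in the mutant than in N2. The log2 changes were 0.602 (3' end, adjusted p = 0.0176), 0.826 (5' end, adjusted p = 0.000458) and 0.716 (middle, adjusted p = 0.000472), with mean signals of 604, 294 and 794 in N2 and 935, 530 and 1330 in the mutant. With skn-1 RNAi the changes were -0.371 (adjusted p = 0.139), -0.988 (adjusted p = 0.000115) and -0.91 (adjusted p = 6.3e-05). The catalase gene ctl-2 did not pass the test in the mutant (0.05, adjusted p = 0.778). Which catalase transcript the control probe sets detect was not tested.

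Other divisions of the same arrays into groups of the same sizes argue against chance for the first 2 comparisons but do not exclude it. With 35 divisions the lowest possible share is 1 of 35. Differences of culture, stage or batch that run with the groups are not addressed by these divisions. The real division was the only 1 of 35 to call as many probe sets for mutant against N2 (4344, highest other 6) and the only 1 of 35 for skn-1 RNAi against control RNAi (3558, highest other 49). For the mutant with skn-1 RNAi against N2 (1001, highest other 0, real division 1 of 10), the 10 divisions are too few for a share under 0.05.

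Genes that rose at least 8-fold in the mutant returned to very different degrees with skn-1 RNAi. Of 58 such genes, 18 kept at least 50% of their log2 rise and 20 kept 10% or less (median 30.5%, interquartile range 63.5), with gst-12 at 90.1% and gst-30 at 88.3% against gst-38 at 7.61% and F55G11.2 at 0.0287%. Of the rise in mean signal, without log or pseudocount, 3 kept at least 50% and 30 kept 10% or less (median 9.1%, gst-12 at 66.6% and gst-30 at 55.5%). Saturated signals alone are argued against, since the interquartile range of the log2 share was 55.2 among the 42 genes with a mutant signal under 5000. It was 64.4 among the 51 genes with an unsuffixed probe set, so suffixed probe sets alone do not account for the spread. Leaving out so few of the 58 genes could hardly narrow it. Signal shared between related genes on unsuffixed probe sets was not tested and stays open. That stronger induction leaves more behind when skn-1 is only partly knocked down may add to the spread but stays open (Spearman's rho 0.256, Pearson's r 0.268, permutation p = 0.0529, across genes, which are not independent replicates). The share is a ratio to the same log2 rise, which can itself shape this correlation. For the share of the rise in mean signal Spearman's rho was 0.14. Control by factors other than SKN-1 was not tested.

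The moulting and sperm lists were called higher in the mutant while the oocyte, yolk and replication lists were called lower. With an estimated correlation none of the 5 was called (adjusted p = 0.203, 0.225, 0.203, 0.297 and 0.123). For the moulting and oocyte lists array scaling is argued against, since after quantile normalization and median centring the lowest median of the moulting list was 0.327 and the highest of the oocyte list -0.281. The sperm median fell from 0.297 to 0.0962 with median centring, with 16 up and 4 down, so scaling may add to the sperm part, which stays open. Younger animals in the mutant cultures could give this pattern. Within groups, arrays with higher moulting genes had lower oocyte genes (r -0.465, permutation p = 0.247, Spearman's rho -0.491, permutation p = 0.238, 10 arrays, 1 of 10 pairs of lists, and -0.609 without N2 replicate 1 and wdr-23 control RNAi replicate 2), which with 10 arrays decides nothing. Of the 10 pairs of lists none passed after adjustment (lowest adjusted p = 0.221). Some ran as younger animals would give, as moulting with yolk (r -0.675, permutation p = 0.0664, Spearman's rho -0.661, permutation p = 0.0776) and oocytes with replication (r 0.801, permutation p = 0.0252, Spearman's rho 0.697, permutation p = 0.0606). Moulting with sperm, both higher in the mutant, ran opposite (r -0.575, permutation p = 0.163, Spearman's rho -0.442, permutation p = 0.323). The permutations took no account of replicate number, although N2 and wdr-23 skn-1 RNAi arrays of the same number ran alike. Mean log2 values of the yolk list were 13.41, 13.28 and 13.05 in N2 replicates 1, 2 and 3. In wdr-23 skn-1 RNAi they were 13.42, 13.25 and 13.11, so these p values may be too small. With skn-1 RNAi and the preset correlation the moulting list was called lower and the oocyte, yolk and replication lists higher. The sperm list was not called there (median 0.0846, camera adjusted p = 0.168). It remained higher than N2 (21 of 78 up, median 0.286), so the sperm part did not follow the other lists. The explanation by younger animals stays open. A change of timing caused by loss of wdr-23 is equally open and was not tested.

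Among genes changed at least 2-fold in the mutant, 68 were still changed the same way against N2 with skn-1 RNAi and were not called between the RNAi treatments. Variants carried along with the wdr-23 mutation might leave such genes. Of 64 with a place in the gene order, 2 lay among the 400 genes nearest to wdr-23, where 1.75 were expected (odds ratio 1.15, 95% interval 0.135 to 4.36, one-sided Fisher's exact test not passed). That interval leaves the explanation open for these genes, though 62 of the 64 do not lie near wdr-23.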

How the results depend on the processing

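Chosen after seeing the data, and given in the closing parts, were the share of the rise in signal, the stage correlation without 2 arrays and the family counts under other scalings. Among called gene lists, 11 of 16 (mutant against N2), 12 of 17 (skn-1 RNAi against control RNAi) and 10 of 20 (mutant with skn-1 RNAi against N2) kept their call under every alternative run on them, except those to the set test. Among named genes with a call, 142 of 166, 128 of 152 and 65 of 100 did, and 0 reversed. Not every alternative reached every result: of 195 named genes 160 were tested with the lowest 50% left out and fewer without suffixed probe sets, where 31 of 34 lists were tested. The cause of the changes below was not tested unless it is given.

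With a pseudocount of 76, which shrinks the changes of dim probe sets by construction, the counts changed at least 2-fold were 363 higher and 84 lower in the mutant, 52 and 258 with skn-1 RNAi, and 65 and 46 for the mutant with skn-1 RNAi against N2. Median centring, which shifts all changes of a comparison together, gave 1671 higher and 4613 lower in the mutant (217 at least 2-fold lower), 3463 higher and 1308 lower with skn-1 RNAi (133 at least 2-fold higher), and overlaps of 876 (rose then fell) and 2695 (fell then rose). Without suffixed probe sets fewer were tested. The counts were 1834 higher and 890 lower in the mutant, 835 and 1266 with skn-1 RNAi (53 and 267 at least 2-fold) and 385 and 214 in the comparison of the mutant with skn-1 RNAi and N2. The overlaps were 877 and 459, and 11 lists were called in that last comparison. There the body-wall muscle median turned to 0.078, and the mean direction of the intestine list reversed (median -0.11). With 1 probe set per gene, 53 were at least 2-fold higher with skn-1 RNAi.

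At an adjusted p under 0.01 in both comparisons the overlaps were 807 and 287, and at 2-fold or more in both 301 and 45. With an estimated correlation camera called 2, 5 and 7 lists. The fry test called 28 (directional) and 33 (mixed) in the mutant, 27 and 33 with skn-1 RNAi, and 16 and 29 for the mutant with skn-1 RNAi against N2.

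Leaving out 1 array at a time gave 890 to 1557 lower in the mutant, 884 to 1573 higher with skn-1 RNAi, 298 to 637 higher and 223 to 406 lower for the mutant with skn-1 RNAi against N2, and a fell-then-rose overlap of 514 to 868, with fewer samples in each fit. The lowest were without N2 replicate 1 for the first, without wdr-23 skn-1 RNAi replicate 1 for the second and last, and without its replicate 3 for the others. What signal over background limits was not measured, and the 30% of probe sets left out as dim (5.71 or less) were not tested.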

Other observations

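The families, gene sets and tests in this part were all chosen only after the results were seen.

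Gene families were taken by the prefix of the gene name. In the mutant, 20 of 24 flp genes, which encode FMRFamide-like neuropeptides, rose (Fisher's exact test, adjusted p = 3.44e-09 over 714 tests), and 15 of the 24 fell with skn-1 RNAi (adjusted p = 2.58e-06). Quantile normalization gave 15 and 15, and median centring 14 and 9. The bus genes, which act on the cuticle surface, rose in 8 of 10 cases (adjusted p = 0.00293) and fell in 6 with skn-1 RNAi (adjusted p = 0.0222). Under both other scalings these were 5 and 5. The skr genes, which encode Skp1-related ubiquitin ligase subunits, fell in 9 of 18 cases (adjusted p = 0.0017) and rose in 7 with skn-1 RNAi (adjusted p = 0.0331), which became 11 and 9 after quantile normalization and 13 and 12 with median centring. The npp genes of the nuclear pore rose with skn-1 RNAi in 12 of 25 (adjusted p = 0.000119), against 8 and 16 with those scalings. The enrichment was tested only with the deposited scaling. Fisher's exact test takes the genes of a family as independent, which genes that move together are not, so the family p values may be too small. The neuropeptide list, which holds the flp genes, was not called by camera with an estimated correlation (adjusted p = 0.131 in the mutant and 0.138 with skn-1 RNAi). Of 95 clec genes, 29 rose and 19 fell in the mutant, with a median of 0.19 that turned to -0.01 with median centring. The counts became 19 and 21 after quantile normalization and 19 and 26 with median centring. With skn-1 RNAi 25 clec genes fell (adjusted p = 0.0172) and 11 rose, and 14 were below N2 (adjusted p = 1.21e-05) and 6 above. Quantile normalization gave 24 and 12, and 14 and 3, and median centring 20 and 14, and 15 and 3. Among genes raised at least 8-fold in the mutant, 14 gst genes kept a median of 68.6% of their log2 rise with skn-1 RNAi and 6 clec genes 10.3%, a difference of 58.3 points (exact permutation test, two-sided, p = 0.00219, 38760 arrangements, across genes, which are not independent replicates). Of the rise in mean signal, without log or pseudocount, the medians were 36.3% and 1.05%, a difference of 35.2 points (exact permutation test, two-sided, p = 0.0198).

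Some changes in the mutant were not called between the RNAi treatments and still differed from N2, which does not show that skn-1 RNAi left them alone. Of 68 such genes, 42 were higher and 26 lower. Among them F57A10.2 was at 2.87 in the mutant and 2.77 with skn-1 RNAi (both against N2), gst-29 at 1.35 and 1.49, acl-12 at -1.54 and -1.71, and the desaturase gene fat-7 at -1.07 and -1.11. Other genes had no call in the mutant, changed at least 2-fold with skn-1 RNAi and were called the same way against N2, though the difference between the comparisons was not tested. Of 24 such genes, 19 fell, among them the ferritin gene ftn-1 (-1.65), F28F5.4 (-1.62), R07E3.4 (-1.53) and tts-1 (-1.17), and 5 rose, K09C6.9 (2.58), lys-10 (1.91), ddn-1 (1.64), Y46G5A.20 (1.31) and nlp-25 (1.12). In 21 genes skn-1 RNAi moved expression further from N2 in the direction of the mutant, 9 higher and 12 lower, including K10D11.2 (1.94 in the mutant and 2.56 after skn-1 RNAi) and fat-5 (-1.38 and -1.999).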
